A study of Rattus norvegicus with 10 samples.

How the data were processed

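RNA from pooled dorsal skins of rats had been hybridised to an Affymetrix rat genome array, with 10 arrays and 8739 probe sets in the table. Each array held total RNA from 1 pool of skins, and the labels gave the number of rats for only the 9 Gy pool at 1 day and the control pool at 28 days of age (4 rats each). The deposited values were intensity per probe set, in whole numbers. The authors had scaled each array to a common mean of 4792 over all probe sets, as the values showed, and the processing software was not given in the sources used here. In the 5 arrays of the early set nearly all deposited low values stood at exactly 1 (1787 to 2044 per array), and 0 to 9 per array were 0. In the 5 arrays of the 35-day set negative values had been kept, with 1940 to 2045 values below 1 per array. Median deposited intensity per array lay between 607 and 850. The number of arrays limited the precision.

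The early set was the control at 28 days of age, skin at 1 day after 9 Gy, skin at 24 hours after 18 Gy, skin of vitamin A fed rats whose label gave no age, and skin of vitamin A fed rats at 24 hours after 9 Gy. The 35-day set was the 2 control pools at 35 days of age, skin at 1 week after 9 Gy, vitamin A fed skin at 35 days of age, and vitamin A fed skin at 1 week after 9 Gy. Vitamin A pools are called fed and the others unfed. The label of the 18 Gy pool did not name a diet, and it was taken as unfed. Apart from the 2 control pools at 35 days, each of the 9 groups held 1 pool, so no SD within a group was available elsewhere.

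The trimmed mean of each array, leaving out 2% of values at each end, differed between arrays by a ratio of up to 1.19, above the allowed 1.05, so the arrays were quantile normalized. Values were then raised to a floor of 49.9, the 25th percentile of all values, and log2 transformed. Probe sets were tested if their mean lay at or above the 40th percentile of probe set means, which left 5243. Of all probe sets, 7005 mapped to 1 gene symbol, 308 to several and 1426 to none, and the tested ones with 1 symbol (4312) covered 3208 genes. A gene named for its own change that had several tested probe sets was represented by the one with the smallest p. Members of gene lists, and the genes named in every comparison of a kind, were represented by the probe set with the highest mean over all arrays. Levels in the text are normalized intensities, and a level printed as the floor was at or under 49.9.

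Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and Benjamini-Hochberg adjustment over the probe sets tested at a false discovery rate of 0.05. Irradiation and vitamin A within a set came from an additive fit with separate effects in each set (7 coefficients, 3 residual degrees of freedom). In that fit the change after 18 Gy was taken against the unirradiated unfed level of the early set as estimated from the control, vitamin A and 9 Gy pools together. The change after 9 Gy averaged the unfed and the fed pair of a set, and the spread came from how the pairs differed and from the 2 control pools. Effects common to both sets came from fits with 6 coefficients and 4 residual degrees of freedom. Interactions of vitamin A with 9 Gy, and age, came from a fit with a mean for each of the 9 groups, whose 1 residual degree of freedom came from the 2 control pools, each lone pool being assumed to vary like the others. The p-values therefore rested on a spread between pools, which outside the fit with a mean per group also held any real difference between the pairs. Nothing in the labels said how far that spread was between animals. The size of the 9 Gy response was compared between fed and unfed pairs without a test, over the 200 probe sets with the smallest p at each time.

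For 26 gene lists, camera from limma compared the members with all other genes at its preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation. None of the calls with the preset correlation held with an estimated correlation. Members past the threshold were counted over all probe sets and adjusted over the list alone. Medians of a list in a single pair of pools were set against 10000 random lists of the same size. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per comparison, the 10 largest rises and the 10 largest falls past the threshold with the same sign in each matched pair, or the 10 probe sets with the smallest p if fewer than 10 passed, up to 4 members of each list, and Cdkn1a, Mdm2, Ccng1, Gadd45a, Crabp2 and Aldh1a1. Bax, Rarb and Tgm2 were also on that rule and had no tested probe set with 1 symbol, and another item on it is not reported here. Members of lists that camera did not call are left out of the text unless another part of the rule named them, and so are some of the remaining genes of long sets.

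The fits were tested on simulated data, with 200 changed probe sets in each of 50 simulations per size and the spread of these arrays. Of simulated changes of 2 on the log2 scale, 70.2% were recovered for 9 Gy at 1 day, 74.1% for 9 Gy at 1 week, 52.6% for 18 Gy and 86.1% for vitamin A over both sets, with false calls making up 4.95% to 6.28% of the calls. Of changes of 1, 14.6%, 21.6%, 0.07% and 54.7% were recovered, with false calls of 5.09% to 10.5%. The fit with a mean per group did not hold its false discovery rate. With no simulated change it made calls in 19 of 50 simulations for the interaction at 1 day, in 25 for the interaction at 1 week and in 21 for age. At a simulated change of 2 its false calls were 19.1%, 13.1% and 10.3% of the calls, and it recovered 4.35%, 12.3% and 49.5% of the changes. At a change of 1 false calls were 54.1%, 32.9% and 23.4%, and 0.25%, 0.08% and 1.33% were recovered. In 1 simulation, 20 genes of 1 list were shifted by 0.50. Camera called that list with the preset correlation (adjusted p = 1.20e-10) and not with an estimated correlation (adjusted p = 0.125). It called none of the 25 unshifted lists with either. Genes were simulated without correlation between them. The simulation therefore cannot show whether the preset calls hold for lists whose genes vary together. Each probe set was also given the same spread on all simulated arrays. In the data the median residual SD was 0.29 in the early set and 0.20 in the 35-day set. The false calls of a fit whose spread came from the 35-day controls alone may therefore be understated.

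Alternatives were scaling to a common trimmed mean, values as deposited, a floor at the 40th percentile, an added constant in place of a floor, no filter, a stricter filter, no intensity trend, a robust prior, a fit with a mean per group, the mean over probe sets of a gene, an estimated correlation, and leaving out each array. Setting values below 1 to 1 on every array was chosen after seeing the data. No sample was left out of the fits.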

Results

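Gene expression was measured in rat dorsal skin after irradiation, with and without vitamin A in the diet, on 10 arrays that each held 1 pool of skins. An early set of 5 pools held an unirradiated control at 28 days of age, in the resting stage of hair growth by its label, and skin at 1 day after 9 Gy and at 24 hours after 18 Gy. It also held vitamin A fed skin without irradiation and at 24 hours after 9 Gy. The labels of the 18 Gy pool and of the fed pool at 24 hours after 9 Gy named electron irradiation. A 35-day set held 2 control pools at 35 days of age, skin at 1 week after 9 Gy, vitamin A fed skin at 35 days of age and vitamin A fed skin at 1 week after 9 Gy. Every group but the 35-day control was a single pool (n = 1), so errors below are standard errors (SE) of fits over all 10 arrays. Median deposited intensity ranged from 607 to 850 per array. Across the 5243 probe sets tested, log2 levels correlated at 0.822 to 0.913 within the early set, 0.911 to 0.949 within the 35-day set and 0.762 to 0.853 between the sets. These are correlations across genes, which are not independent replicates. The 2 control pools differed by a median SD of 0.13 on the log2 scale, and 358 probe sets differed between them by more than 1.

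The comparison at 1 day asked how skin responded to 9 Gy soon after irradiation, averaged over unfed and vitamin A fed rats. Klk6, an epidermal serine protease of the kallikrein family, rose by 3.92 on the log2 scale (SE 0.47, limma adjusted p = 0.0437), from 1557 to 49776 in the unfed pair and from 3661 to 26275 in the fed pair. Serpinb3a, an epithelial protease inhibitor, rose by 3.55 (SE 0.47, adjusted p = 0.0492). The retinoid binding protein genes Rbp2 and Crabp2 rose by 3.32 (SE 0.42, adjusted p = 0.0480) and 1.27 (SE 0.14, adjusted p = 0.0428), with Crabp2 2.66-fold higher in the unfed pair and 2.19-fold higher in the fed pair. Gpr15lg, a chemoattractant peptide of epithelia, was at the floor in both unirradiated early pools. It was at least 205-fold higher after 9 Gy in the unfed pair and at least 69.3-fold higher in the fed pair (adjusted p = 0.0492), while its other probe set was at 2.06 (adjusted p = 0.157). Nqo1, a quinone reductase of the antioxidant response, rose by 1.90 and the lysosomal protease Ctsd by 1.09.

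In all, 37 of 5243 probe sets passed the threshold at 1 day after 9 Gy, 23 higher and 14 lower, and 949 had an unadjusted p under 0.05 against 262 expected by chance. Hpd rose by 4.00. Other rises had at least 1 unirradiated early pool at the floor. In the unfed and the fed pair, Pdzk1ip1 was 26.9-fold and at least 37.7-fold higher, Galnt6 22.2-fold and at least 34.2-fold, and RT1-DMa 8.58-fold and at least 14.1-fold. Cast was at least 17.2-fold and 18.1-fold higher, and Lgals9 at least 17.3-fold and 10.4-fold. On the log2 scale, other probe sets of Cast (-0.34 and 0.22), Hpd (2.73), Lgals9 (-0.42), RT1-DMa (0.08) and Ctsd (1.20) did not pass. Among the falls, Gabra2, a GABA receptor subunit, went from 1539 to 97 in the unfed and from 1434 to 67 in the fed pair. Tac1, the substance P precursor, went from 872 to 70 in the unfed pair and from 465 to the floor in the fed pair. Others were Eef1a2 (-1.49), the matrix protein gene Sparc (-1.45), the muscle genes Myh7 (-1.27), Mybpc2 (-1.00) and Pvalb (-0.94), the mast cell protease gene Mcpt1l1 (-1.12) and Gpx3 (-1.02). Among 4 probe sets of Sparc, another fell by 1.10 and the remaining values were -0.34 and 0.02. The other probe sets of Myh7 (-3.54) and Gpx3 (-0.75) did not pass. The count was 0 when any array of the 35-day set was left out (either control, 9 Gy at 1 week, vitamin A, or vitamin A with 9 Gy). It was 405 without the early vitamin A pool and 428 without the vitamin A pool at 1 day after 9 Gy, where the change rested on 1 pair of pools and the spread came from the 35-day set alone (median residual SD 0.20, against 0.29 in the early set). It was 8 without an intensity trend in the variance and 0 in the fit with a mean per group. It was 30 (22 higher, 8 lower) with scaled values and 29 (23 higher, 6 lower) with values as deposited.

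**Figure D1:**
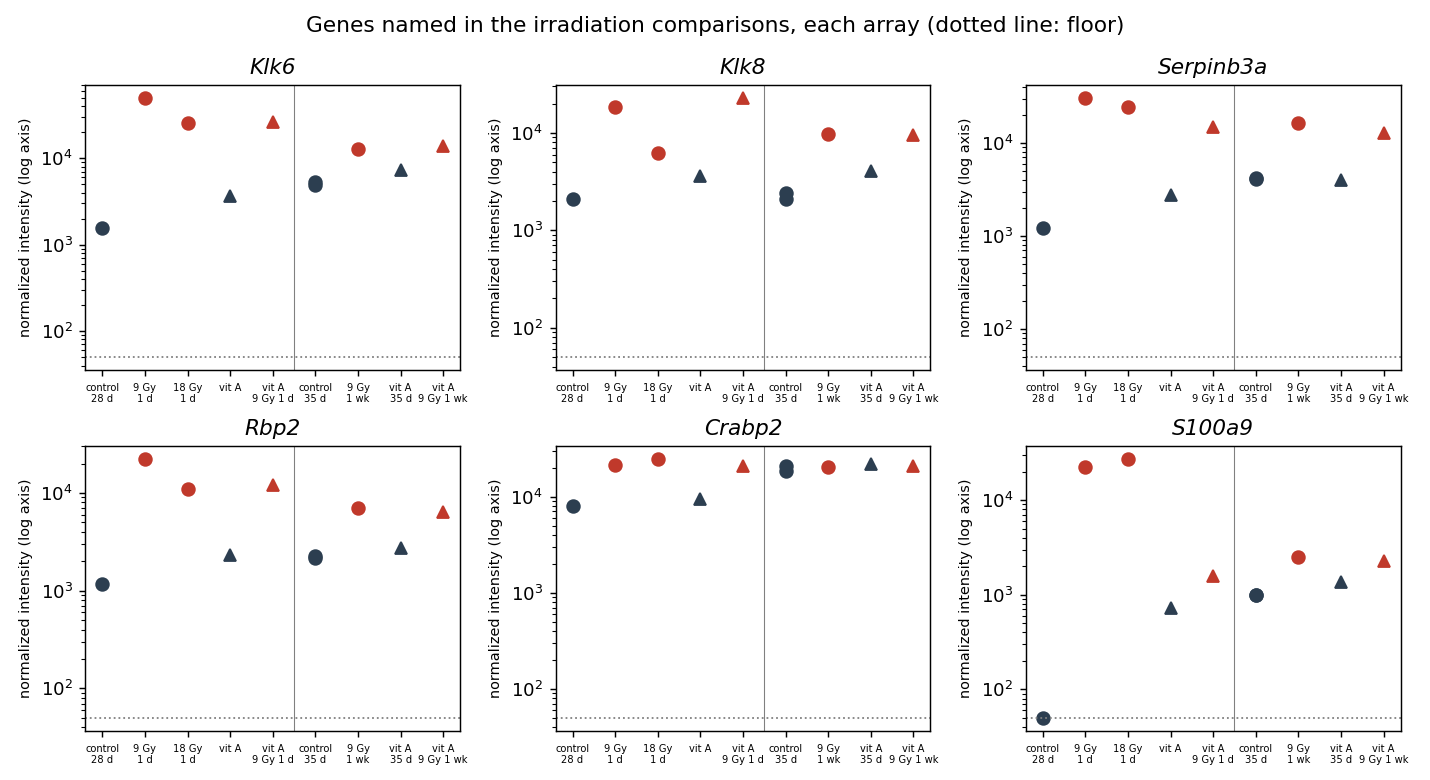
Normalized intensity (log scale) of 6 genes in each of the 10 arrays, with circles for unfed and triangles for vitamin A fed pools, red for irradiated pools and a dotted line at the floor. Klk6 stood at 1557 in the 28-day control, 49776 after 9 Gy and 25811 after 18 Gy.

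At 1 day after 9 Gy camera called 8 gene lists with the preset correlation and 0 with an estimated correlation. Of 19 epidermal keratinocyte genes 17 had positive changes, with a mean of 0.79 (camera adjusted p = 3.26e-06; adjusted p = 0.411 with an estimated correlation). Klk6 was the member past the threshold over all probe sets, and 4 higher and 1 lower passed when adjusted over the list alone. Of 39 skeletal muscle genes 35 had negative changes, with a mean of -0.46 (camera adjusted p = 5.58e-10; adjusted p = 0.381 with an estimated correlation). 3 fell over all probe sets, and 18 lower and 1 higher passed when adjusted over the list alone. Collagen and matrix genes had a mean of -0.56 over 29 members (camera adjusted p = 4.99e-06; adjusted p = 0.381 with an estimated correlation), with 4 lower adjusted over the list alone. Sterol and fatty acid synthesis genes had a mean of 0.54 over 21 members (camera adjusted p = 0.00304; adjusted p = 0.381 with an estimated correlation), with 4 higher adjusted over the list alone. Cyp51, a sterol demethylase, was at 1.20 (SE 0.17, adjusted p = 0.0501) and Sqle, squalene epoxidase, at 1.06 (SE 0.18, adjusted p = 0.0748). Camera also called lower lymphocyte (mean -0.92), mast cell (-0.58) and red blood cell genes (-0.57) and slightly higher ribosomal protein genes (0.09), at adjusted p = 0.0169, 0.0337, 0.00304 and 0.0337. These gave adjusted p = 0.381 (0.396 for red blood cells) with an estimated correlation. Without a filter on dim probe sets the lymphocyte mean was -0.16 (camera adjusted p = 0.795). Without the 28-day control the epidermal mean was 0.27 (camera adjusted p = 0.0598), and without the unfed 9 Gy pool it was 0.27 (camera adjusted p = 0.0633). Without the vitamin A pool 5 lists were called, and without it or the fed 9 Gy pool the calls ended for the sterol (0.43 and 0.41), lymphocyte (-0.53 each) and red blood cell lists (-0.38 each). The mast cell call ended without the unfed 9 Gy pool or the 28-day control (-0.37 each) and without either vitamin A pool (-0.79 each). The ribosomal call ended without the unfed 9 Gy pool (-0.018), the 28-day control (-0.014) or the vitamin A pool (0.20).

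Targets of p53, the damage-response regulator, showed no common direction at 1 day after 9 Gy, with a median of 0.07 over 9 genes (camera adjusted p = 0.620). Cdkn1a was at 1.61 (SE 1.25, adjusted p = 0.537), Mdm2 at 0.80 (SE 0.33, adjusted p = 0.277), Ccng1 at -1.33 (SE 0.46, adjusted p = 0.221) and Gadd45a at -0.25 (SE 0.30, adjusted p = 0.712). Cdkn1a was at the floor in the 28-day control, at 813 after 9 Gy, 378 after 18 Gy, and 597 and 342 in the fed pools without and with 9 Gy. These values are from 1 probe set, which was at 4.76 for control at 35 days minus control at 28 days. Another tested probe set of Cdkn1a was at -2.60 there, so the low level in the 28-day control was not shared by both. Leaving out the 28-day control or the unfed 9 Gy pool turned Cdkn1a to -0.81, and leaving out either early vitamin A pool turned Gadd45a to 0.33. At 18 Gy the values were 1.72 for Cdkn1a, 1.49 for Mdm2, -1.12 for Ccng1 and 0.32 for Gadd45a (adjusted p from 0.399 to 0.909). Without the 28-day control they turned to -1.93 for Cdkn1a, 0.48 for Ccng1 and -0.55 for Gadd45a. At 1 week after 9 Gy they were -1.31, -0.19, 0.21 and -0.46 (adjusted p from 0.881 to 1.00), with Mdm2 at 0.26 without either vitamin A pool of the 35-day set.

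The 18 Gy pool was compared with the unirradiated level of the early set, as fitted from the 4 other early pools, to ask how skin responded to a higher dose at 24 hours. The epidermal genes had a mean of 0.74 over 19 members, with Klk6 at 3.51 (SE 0.62, adjusted p = 0.212). Cell cycle and DNA replication genes were lower, with a mean of -0.46 and negative changes in 24 of 30 (Plk1, a mitotic kinase, -1.35; Pcna, the replication clamp, -0.91). Camera called both lists (adjusted p = 5.17e-05 each; adjusted p = 0.583 with an estimated correlation). Adjusted over the list alone 3 epidermal genes were higher and no cell cycle gene passed. MHC class II genes had a mean of -0.46 (camera adjusted p = 0.0291; adjusted p = 0.583 with an estimated correlation). Crabp2 was at 1.57 (SE 0.18, adjusted p = 0.115), Pdzk1ip1 at 2553 against 132 in the 28-day control, the plasminogen activator inhibitor Serpinb2 at 2.39, and Cebpd, a transcription factor of the acute phase response, at -2.75, none past the threshold. The probe set that passed, among 471 with an unadjusted p under 0.05, was for Map2k2, at the floor in the 18 Gy pool and between 3095 and 6603 elsewhere (adjusted p = 0.0227). Its other 2 probe sets were at 0.23 and 0.12. Without the 28-day control, which the 9 Gy and 18 Gy contrasts share, the means were -0.036 for the epidermal list and -0.11 for the cell cycle list (adjusted p = 0.956 and 0.673) and no probe set or list passed. The MHC class II call also ended without the unfed 9 Gy pool or either vitamin A pool (-0.38 each). The count of 1 became 0 without any array of the 35-day set, 134 without the unfed 9 Gy pool, 126 without the vitamin A pool and 123 without the fed 9 Gy pool, the last 3 with the spread of the 35-day set alone.

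The 18 Gy pool was then set against the unfed level after 9 Gy, as fitted from the other early pools together. It had higher levels of muscle genes (mean 0.54, 36 of 39 positive, with Ckm, muscle creatine kinase, at 0.67, SE 0.14), collagen and matrix genes (0.49), matrix proteases and inhibitors (0.38, with Mmp3, a matrix metalloproteinase, at 2.16, SE 0.47) and red blood cell genes (0.40). It had lower levels of sterol synthesis genes (-0.56; Cyp51 -1.02, SE 0.23), MHC class II genes (-0.55; Cd74, the invariant chain, -1.30, SE 0.28) and cell cycle genes (-0.29; Pcna -1.08, SE 0.25). Camera called these 7 lists at adjusted p from 5.93e-10 to 0.0423, and adjusted p = 0.281 to 0.380 with an estimated correlation. Adjusted over the list alone, 3 MHC class II genes were lower and no member of the other lists passed. Of single probe sets, 1 passed with limma (Map2k2) and 533 had an unadjusted p under 0.05. Without the unfed 9 Gy pool 49 passed, without the 28-day control 27, without either early vitamin A pool 13 (each with the spread of the 35-day set alone), and without any array of the 35-day set 0. Without the unfed 9 Gy pool 4 lists were called, the means being -0.32 for MHC class II, 0.16 for matrix, 0.61 for protease and 0.68 for red blood cell genes, which no longer passed. The cell cycle, protease and red blood cell calls also ended without the 28-day control (-0.17, 0.31 and 0.30) or either vitamin A pool (-0.13, 0.31 and 0.30), and the protease call without either irradiated or fed pool of the 35-day set (0.38). In the 18 Gy pool minus the unfed 9 Gy pool alone, the means were -0.17 for cell cycle, 0.31 for protease and 0.30 for red blood cell genes.

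At 1 week after 9 Gy, where the question was what remained of the response, most genes that passed were muscle genes. Myl2, the slow and cardiac myosin light chain, rose by 2.72 (SE 0.20, adjusted p = 0.0155), the sarcomere genes Actn2 by 2.00 and Csrp3 by 3.08, Myh2, the myosin of oxidative fast fibres, by 2.02, the small heat shock protein gene Hspb6 by 1.30 and filamin C (Flnc) by 2.30 (adjusted p from 0.0155 to 0.0464). Of other probe sets, 1 of Myl2 also rose (4.31), and those of Hspb6 (1.04), Flnc (0.99) and Myl2 (2.03) did not pass. Myh4, a fast myosin heavy chain, fell by 1.34 (SE 0.11, adjusted p = 0.0155) and Pvalb, the calcium buffer parvalbumin, by 1.02 (SE 0.11, adjusted p = 0.0464). Actn2 was 4.05-fold higher in the unfed pair and 3.91-fold higher in the fed pair, and Myh4 stood at 34357 and 26817 in the irradiated pools against 70575 to 90751 in the 3 others. Csrp3 stood at 599 to 677 in the unirradiated 35-day pools, 4659 and 6928 at 1 week after 9 Gy, and 2165 to 5258 in the early pools. For Actn2 these levels were 3939 to 5668, 16714 and 22180, and 9232 to 21012. A low unirradiated level at 35 days was therefore not told apart from a rise after 9 Gy. Of the 39 muscle genes 27 were positive, with a mean of 0.45 (camera adjusted p = 0.000132; adjusted p = 0.743 with an estimated correlation). Of these 2 were higher and 2 lower over all probe sets, and 12 higher and 3 lower when adjusted over the list alone.

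**Figure D2:**
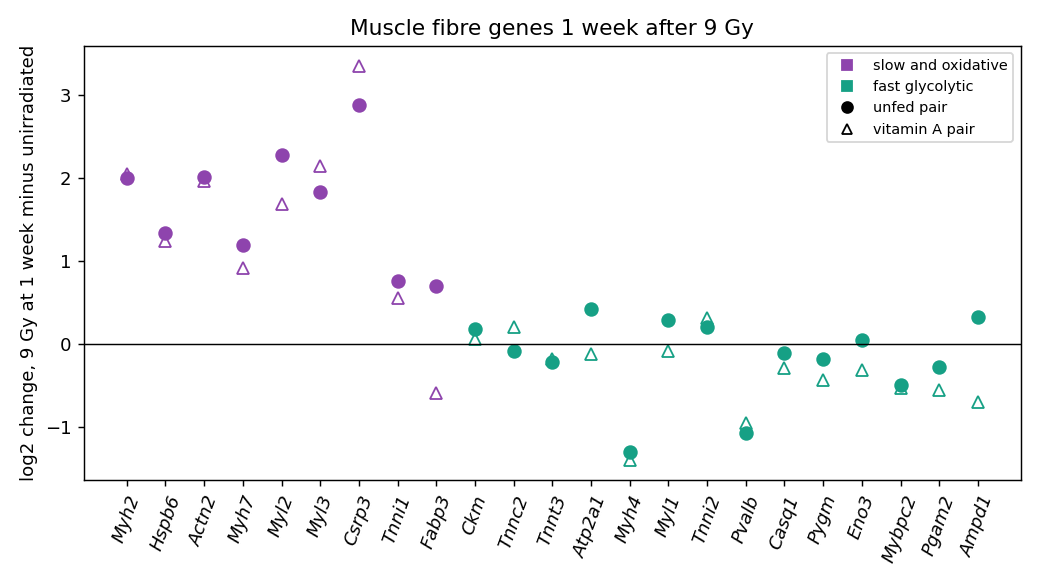
Log2 change at 1 week after 9 Gy of each measured slow or oxidative and fast glycolytic fibre gene, in the unfed and the vitamin A fed pair, with the lists of fibre genes drawn up after the data were seen. The median of the 9 slow and oxidative fibre genes, Myh2 among them, was 1.83 in the unfed and 1.69 in the fed pair, and that of the 14 fast glycolytic fibre genes -0.09 and -0.29.

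All 8 MHC class II genes, which present antigen to helper T cells, were higher at 1 week after 9 Gy, by a mean of 0.85 (camera adjusted p = 5.71e-06; adjusted p = 0.743 with an estimated correlation). None passed over all probe sets and 6 passed adjusted over the list alone, with RT1-Da at 0.61 (SE 0.13) and RT1-Ba at 0.91 (SE 0.25). Macrophage and granulocyte genes were higher by 0.41 over 11 members (camera adjusted p = 0.0277), with lysozyme (Lyz2) at 0.72 (SE 0.16), and collagen and matrix genes by 0.10 (camera adjusted p = 0.00813), with adjusted p = 0.745 for both with an estimated correlation, and 2 members of each higher adjusted over the list alone. In all 10 probe sets passed at 1 week, 7 higher and 3 lower, and 365 had an unadjusted p under 0.05 against 262 expected by chance. The remaining fall was in Synj1, from 503 and 965 to the floor in the unfed pools and from 3510 to 148 in the fed pair. The count was 2 without either 9 Gy pool of the early set, and 0 without the 28-day control, the early vitamin A pool or any array of the 35-day set. It was also 0 without a filter, without an intensity trend and in the fit with a mean per group. Without the unfed pool at 1 week 1 list was called, with means of 0.41 for MHC class II (camera adjusted p = 0.10), 0.25 for macrophage and 0.32 for muscle genes. The macrophage call also ended without control at 35 days replicate 2 (0.38), and the matrix call without either vitamin A pool of the 35-day set (0.029 and 0.028).

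The change after 9 Gy at 1 week minus that at 1 day was 3.97 for Myl2 (SE 0.30, adjusted p = 0.0412), 2.29 for Actn2, 2.35 for Myh7, 2.15 for Myh2, 2.00 for Hspb6 and 1.90 for 1 probe set of Sparc (adjusted p from 0.0412 to 0.0458). It was downward for 1 probe set of Cast and for Synj1. That of Cast was at the floor in both unirradiated early pools, and Synj1 in 1 irradiated pool at 1 week. Other probe sets of Cast (0.094 and -1.06) and Sparc (0.16, 0.43 and 1.37) did not pass, nor did those of Hspb6 (1.61) and Myh7 (5.73) and 1 of Myl2 (5.35). The muscle list differed by a mean of 0.91 and the collagen and matrix list by 0.65 upward, and the epidermal list by -0.58, with camera adjusted p = 4.03e-13, 8.79e-08 and 0.00232, and adjusted p = 0.371, 0.535 and 0.543 with an estimated correlation. Adjusted over the list alone, 18 muscle genes differed upward and 2 downward, 6 matrix genes upward and 2 epidermal genes downward. In all 10 probe sets differed, 8 upward and 2 downward, and 707 had an unadjusted p under 0.05. Cdkn1a was at -2.93, Mdm2 at -0.99, Ccng1 at 1.54 and Gadd45a at -0.22 (adjusted p from 0.369 to 0.838). Gadd45a turned to 0.36 without the 28-day control or the unfed 9 Gy pool, where the epidermal mean was -0.065 and -0.062 and no longer passed. The count was 1 without either of those pools or with scaled values, 6 (5 up, 1 down) as deposited, and 19 without a filter. It was 214 without the early vitamin A pool, 252 without the fed 9 Gy pool at 1 day, both with the spread of the 35-day set alone, and 0 without any array of the 35-day set, without an intensity trend or in the fit with a mean per group.

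Over both sets, the change after 9 Gy passed for Pvalb, at -0.98 (SE 0.09, adjusted p = 0.0350), with 412 probe sets at an unadjusted p under 0.05. The smallest p after it were those of Ctsd (1.03, adjusted p = 0.0672), Klk8, another kallikrein (2.26, adjusted p = 0.113), and Hal, histidine ammonia lyase of the epidermis (1.58, adjusted p = 0.198). Camera called the epidermal (mean 0.47), MHC class II (0.50), macrophage and granulocyte (0.43) and sterol lists (0.25) higher and the red blood cell list (-0.37) lower, at adjusted p from 8.35e-06 to 0.00443, and adjusted p = 0.523 with an estimated correlation. Adjusted over the list alone, 5 epidermal, 2 MHC class II and 2 macrophage genes were higher, 2 red blood cell genes were lower and no sterol gene passed. Cdkn1a was at 0.04, Mdm2 at 0.26, Ccng1 at -0.50 and Gadd45a at -0.36, none past the threshold (adjusted p from 0.723 to 0.993). Pvalb no longer passed when any array other than the 18 Gy pool was left out, with scaled values, without a filter or without an intensity trend. Without the unfed pool at 1 week 8 lists were called, though not MHC class II (0.20), and the macrophage call ended without the 28-day control or the unfed 9 Gy pool at 1 day (0.30 each) and the sterol call without either early vitamin A pool (0.13 and 0.12). Cdkn1a turned to -1.20 without the unfed 9 Gy pool, -1.17 without the 28-day control and -0.05 without the control at 35 days replicate 2, and Ccng1 to 0.068 without either of the first pair.

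Vitamin A feeding was compared with the unfed diet to ask what the supplement changed in skin. MHC class II genes were lower in fed skin in all 8 members over both sets, with a mean of -0.49 (camera adjusted p = 7.49e-05; adjusted p = 0.487 with an estimated correlation), with RT1-Ba at -0.99 (SE 0.22) and RT1-Da at -0.58 (SE 0.13). Collagen and matrix genes were lower in 25 of 29 members, with a mean change of -0.29 (camera adjusted p = 2.50e-06) and the proteoglycan lumican (Lum) at -0.68 (SE 0.14), and muscle genes were higher with a mean of 0.16 (camera adjusted p = 0.00701). Both gave adjusted p = 0.487 with an estimated correlation. Adjusted over the list alone, 4 MHC class II genes and 1 matrix gene were lower and no muscle gene passed. No probe set passed over both sets (limma, smallest adjusted p = 0.661), and 349 had an unadjusted p under 0.05 against 262 expected by chance. The muscle call ended without the unfed or the fed 9 Gy pool at 1 day (0.15 each) or the vitamin A pool at 35 days (0.096), and 5 lists were called without the 28-day control or the early vitamin A pool. The retinoic acid binding protein gene Crabp2 was at 0.10 (SE 0.09) and the retinal dehydrogenase gene Aldh1a1 at -0.28 (SE 0.13).

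**Figure D3:**
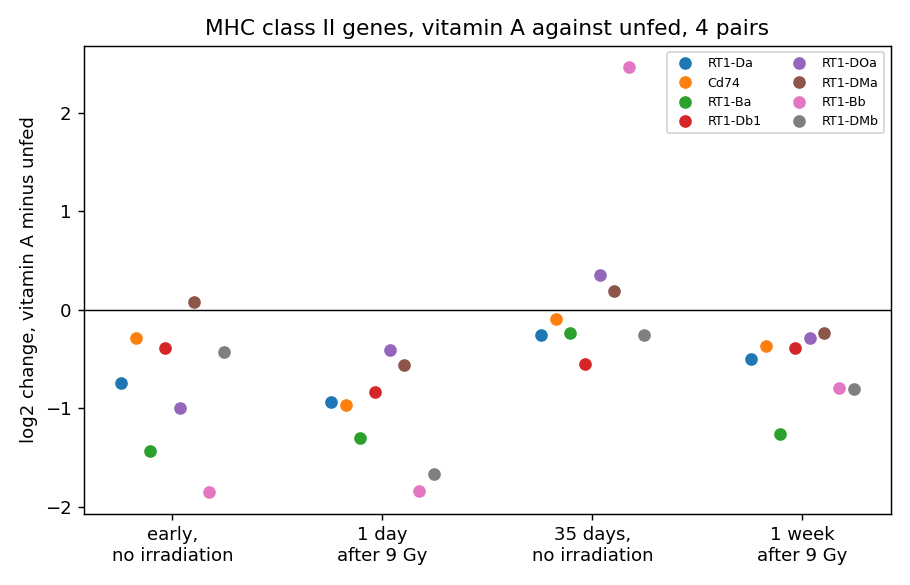
Log2 change with vitamin A of 8 MHC class II genes in each of 4 pairs of pools (fed minus unfed). The medians were -0.59 and -0.95 in the early set without and with 9 Gy, and -0.16 and -0.44 in the 35-day set.

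Within the early set vitamin A gave larger values, with none past the threshold (limma, 679 at an unadjusted p under 0.05). The unirradiated vitamin A pool had no age in its label. It correlated at 0.822 with the 28-day control, 0.848 and 0.852 with the 35-day controls and 0.837 to 0.877 with the other early pools. A difference in age could not be told apart from one in diet in any contrast with this pool, the interaction at 1 day among them. Involucrin (Ivl), a cornified envelope protein, was at 1.71 (SE 0.18, adjusted p = 0.0745), decorin (Dcn) at -0.91 (SE 0.10, adjusted p = 0.0745), Lum at -1.01 (SE 0.11, adjusted p = 0.0745) and the matrix metalloproteinase gene Mmp14 at -2.17 (SE 0.27, adjusted p = 0.0880). MHC class II genes had a mean of -0.91, macrophage and granulocyte genes -0.66 and collagen and matrix genes -0.39 (camera adjusted p = 4.28e-05, 0.0156 and 3.01e-06), all with adjusted p = 0.652 with an estimated correlation, and 5, 3 and 4 of their members were lower adjusted over the list alone. Crabp2 was at 0.13 (-0.074 with values as deposited, and -0.013 without the 28-day control or the early vitamin A pool) and Aldh1a1 at -0.16. The count of 0 became 500 without the unfed 9 Gy pool, 507 without the fed 9 Gy pool, both with 1 pair of pools and the spread of the 35-day set alone, 3 without the 18 Gy pool and 15 without a filter. Without either 9 Gy pool the MHC class II (-0.76 each) and macrophage means (-0.24 each) no longer passed, and without the 28-day control or the vitamin A pool 8 lists were called. In the 35-day set none passed (limma, 216 at an unadjusted p under 0.05; 2 without control at 35 days replicate 1). Camera called muscle genes (mean 0.14) higher and matrix genes (-0.21) lower, both at adjusted p = 0.0165, and adjusted p = 0.972 with an estimated correlation, with no member past the threshold adjusted over the list alone. The muscle call ended without either control (0.12 each) or the vitamin A pool (0.012), and the matrix call without control replicate 2 (-0.16) or the vitamin A pool (-0.11). There Crabp2 was at 0.08 and Aldh1a1 at -0.39.

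Whether vitamin A altered the response to 9 Gy was tested by the interaction, the fed pair's change minus the unfed pair's. At 1 day the epidermal genes had a mean interaction of -1.03 (camera adjusted p = 7.73e-05), with Tgm1, the epidermal transglutaminase, at -3.44 (SE 0.16, adjusted p = 0.111) and keratin 1 (Krt1) at -2.16 (SE 0.11, adjusted p = 0.111), and 10 of 19 members were lower adjusted over the list alone. The 28-day control stood apart in both, with Tgm1 at 635 there and from 4386 to 7864 in the 9 other pools, and Krt1 at 33183 against 92934 to 224566. Macrophage and granulocyte genes were at -0.84, cell cycle genes at 0.47 and matrix genes at 0.44 (camera adjusted p = 0.0416, 0.0195 and 0.0470), with no member past the threshold adjusted over the list alone. These 4 lists gave adjusted p = 0.805 with an estimated correlation. S100a9, an alarmin of neutrophils and stressed keratinocytes, was at the floor in the 28-day control, at 22630 after 9 Gy and at 27403 after 18 Gy, against 728 and 1577 in the fed pools without and with 9 Gy. It was at least 454-fold higher after 9 Gy in the unfed pair and 2.17-fold higher in the fed pair (interaction adjusted p = 0.111). No probe set passed for the interaction at 1 day (limma, 1333 at an unadjusted p under 0.05) or at 1 week (limma, 619), and no list at 1 week. At 1 day 732 passed without a filter, 144 with a stricter one and 4 with a robust prior. At 1 week 308 passed without a filter, in a fit that made false calls on simulated data. The p53 targets did not pass, with Cdkn1a (at the floor in the 28-day control and in the fed 9 Gy pool at 1 week) at -4.83, Mdm2 at 0.54, Ccng1 at 2.12 and Gadd45a at -1.15 at 1 day and -2.19, -1.06, -0.07 and 0.21 at 1 week. Neither did Crabp2 (-0.28 and -0.13) or Aldh1a1 (-0.16, or 0.13 with values as deposited, and -0.28). Over the 200 probe sets with the smallest p the size of the fed pair's response minus that of the unfed pair had a median of -0.12 (SD 0.85 over probe sets) at 1 day and -0.12 (SD 0.68) at 1 week. At 1 day it was 0.0020 with an added constant in place of the floor and 0.016 without a filter, and at 1 week -0.0067 without a filter. The share of probe sets with the smaller change in the fed pair was 57.0% and 64.0%. The probe sets were picked for changes that the pairs shared, and when picked from the fit with a mean per group the median at 1 day was -1.02.

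The unirradiated, unfed skins at 35 and 28 days of age differed in 932 of 5243 probe sets, 591 higher and 341 lower at 35 days (2203 at an unadjusted p under 0.05). The 28-day control was at the floor for Krt36, a hair and nail keratin (at least 120-fold higher at 35 days, adjusted p = 0.0272), for Padi1, a protein-citrullinating enzyme (at least 81.2-fold), and for the urea cycle enzyme Ass1 (at least 222-fold). Epidermal differentiation genes were higher, with Tgm1 up by 2.94 (SE 0.10), Ivl by 2.87 (SE 0.13), the cornified envelope gene Sprr1a by 2.19 and the connexin Gjb2 by 1.75. Of the list, 10 of 19 epidermal genes rose over all probe sets and 15 adjusted over the list alone. Collagen and matrix genes were lower, with 16 of 29 falling and 1 rising over all probe sets (20 and 1 adjusted over the list alone), among them the collagen chaperone Serpinh1 (-3.09, SE 0.13) and Col5a1 (-2.52, SE 0.11). Muscle genes were lower in 12 of 39 (20 lower and 1 higher adjusted over the list alone; Csrp3 -2.21), cell cycle genes in 3 of 30 (9 adjusted over the list alone; Pcna -0.76, with its other probe set at -0.32 not past the threshold) and mast cell genes in 1 of 7 (5 adjusted over the list alone; Cpa3, a mast cell carboxypeptidase, -1.80). Mean changes were 1.04 for the epidermal, -1.12 for the matrix, -0.73 for the muscle, -0.64 for the cell cycle and -1.30 for the mast cell list (camera adjusted p from 2.35e-08 to 0.0121; adjusted p = 0.824 to 0.971 with an estimated correlation). Age, set and a single 28-day pool could not be separated. For Gjb2 the 28-day control stood at 16791, the other early pools at 36526 to 68807 and the 35-day controls at 55356 and 57774. Tgm1 was likewise low in the 28-day control alone, so for these genes the low level was not shared by the early set. The other early pools were irradiated, vitamin A fed or both. Effects of those treatments could therefore not be told apart from a low control or from age. For Ivl the other early pools, at 3827 to 11081, lay between the 28-day control (1934) and the 35-day controls (15126 and 13215). The count was 838 (537 higher, 301 lower) with values below 1 set to 1 on every array. It was 452 with values as deposited (268 higher, 184 lower), 525 without a filter (123 higher, 402 lower), 418 without an intensity trend (290 higher, 128 lower) and 401 with the higher floor (196 higher, 205 lower), in a fit whose false calls on simulated data were 10.3% of its calls at a change of 2 and 23.4% at a change of 1. Those simulations did not include a larger spread in the early set, so these shares may be too low.

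Lists that camera called in none of the 12 comparisons numbered 14. Their smallest adjusted p was 0.0547 for immediate early genes, 0.0654 for heat shock and protein folding, 0.0737 for oxidative phosphorylation, 0.0862 for interferon-induced and MHC class I presentation genes, 0.0976 for cytokines, chemokines and adhesion. It was 0.112 for growth factors and receptors, 0.138 for retinoid metabolism and response, 0.221 for hair follicle markers and 0.236 for apoptosis regulators. It was 0.302 for nerve and Schwann cell markers, 0.314 for p53 targets, 0.369 for antioxidant and glutathione genes, and 0.578 for both adipocyte and endothelial markers.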

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

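The tests of the low 28-day control, of a dim array, of the share of muscle and of leukocytes were chosen after their results were seen, while those of the normalization and of other splits were written beforehand.

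The response to 9 Gy at 1 week was tested directly against that at 1 day, and differed in 10 probe sets. The difference, 1 week minus 1 day on the log2 scale, was 3.97 for Myl2, 2.29 for Actn2, 2.00 for Hspb6, 2.35 for Myh7, 2.15 for Myh2 and 1.90 for 1 probe set of Sparc, and -6.38 for 1 probe set of Cast and -5.36 for Synj1. The other probe sets were at 0.094 and -1.06 for Cast and at 0.16, 0.43 and 1.37 for Sparc. That of Cast was at the floor in both unirradiated early pools and Synj1 in 1 irradiated pool at 1 week, so these sizes depend on the floor. As lists, muscle genes differed by a median of 0.73, collagen and matrix genes by 0.68 and epidermal genes by -0.35. The response to 9 Gy at 1 day also differed between the fed and the unfed pair of pools in 4 lists, by the interaction, with medians of -0.73 for epidermal, -0.77 for macrophage and granulocyte, 0.42 for cell cycle and 0.39 for collagen and matrix genes. These list calls were lost with an estimated correlation. The interaction contains the single 28-day control. The vitamin A pool minus that control had a median of 0.68 for epidermal (random lists -0.23 to 0.21), -0.72 for matrix (-0.23 to 0.20), -0.50 for cell cycle (-0.29 to 0.27) and -0.24 for macrophage and granulocyte genes (-0.58 to 0.52). A 28-day control that stood apart therefore stays open for the epidermal, matrix and cell cycle lists. So does a different age of the vitamin A pool, whose label gave none. For macrophage and granulocyte genes the value lay inside the random range, and a negative value there would raise the interaction. Their median in the fed minus the unfed pool at 1 day after 9 Gy was -1.24.

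Epidermal genes were higher after 9 Gy at 1 day mainly in the unfed pair, by a median of 1.07 against 0.21 in the fed pair. A generally dim or degraded 28-day control array stays open. In the vitamin A pool minus the 28-day control 2 of 26 lists lay above their random range and 4 below, but quantile normalization gave all arrays the same distribution, so this decides nothing. That array had the largest share of tested probe sets at the floor, 2.82% against 1.39% to 2.25% in the others, and also the highest deposited median, 850. A control pool that was low in epidermal genes, whatever the irradiation, stays open: with it left out the mean change of the list was 0.27 against 0.79 with all arrays (camera adjusted p = 0.0598). That value comes from the fed pair alone, and leaving out the unfed 9 Gy pool gave 0.27 as well, so it does not separate a low control from a response in the unfed pair. That test replaced an earlier one, also chosen after the values were seen, in which the unfed 9 Gy pool exceeded the unirradiated vitamin A pool by a median of 0.26 (random lists -0.22 to 0.17); it would have argued against a low control, and was replaced because it rested on a single reference pool. An effect of irradiation and one of vitamin A on this list cannot be told apart from a low control with 1 pool per group.

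At 1 week after 9 Gy, slow and oxidative muscle fibre genes were higher by a median of 1.96 (9 of 9 higher), and fast glycolytic fibre genes were at -0.14 (9 of 14 lower). These are changes fitted over both pairs, and Fabp3 was at 0.70 in the unfed and -0.58 in the fed pair. The lists of fibre genes were drawn up after the data were seen, with 5 of the slow and oxidative and 2 of the fast glycolytic genes already past the threshold, and 7 and 14 of them also in the muscle list. Those outside it were the sarcomere gene Actn2 and the small heat shock protein gene Hspb6, both already past the threshold. Without Myh2, an oxidative fast fibre myosin, the slow and oxidative median was 1.63. A permutation test of the gene labels was set aside, since some genes had been chosen for the pattern, and the medians were compared with the SD over genes instead. A larger share of the same muscle in the irradiated pools would raise both kinds alike. For the genes of these lists, the fast glycolytic median of -0.14 argues against it (SD over genes 0.46, and 0.88 in the other list). That comparison shares the late choice of genes and is not an independent test. Compression by quantile normalization is argued against by a difference between the medians of 2.09 with values as deposited, against 2.11. Scaled values also gave 2.09, but scaling an array cancels in this difference, so they are no second check. Skin taken over a different part of the muscle layer was not tested and stays open, as does a shift of fibre genes in the irradiated muscle, which is a hypothesis. Csrp3 and Actn2 were lower in the unirradiated 35-day pools than in any early pool, so a low reference level at 35 days stays open as well.

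MHC class II genes were lower with vitamin A in each of 4 pairs, with medians of -0.59, -0.95, -0.16 and -0.44. Normalization is argued against, as the mean was -0.49 with scaled values and -0.53 as deposited. Fewer leukocytes in the fed pools stay open: both leukocyte lists had a median below 0 in 3 of 4 pairs, and in the early unirradiated pair the lymphocyte median was 0.17 while that of macrophages and granulocytes was -0.24. A lower expression of these genes per cell and fewer cells that express them cannot be told apart in pooled whole skin.

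The real split and other splits of the same arrays were fitted alike, 100 in all, with the others drawn with a fixed seed. The other splits were drawn over both sets together, while the real fed and irradiated pools were spread over each set. They therefore did not keep the layout of the real groups. For vitamin A over both sets, where 0 probe sets passed with limma (349 at an unadjusted p under 0.05), 100 of 100 splits gave as many, which any split does against 0 and says nothing, and the highest other gave 457. For 9 Gy over both sets, where 1 passed, 18 of the 100 splits, the real one included, gave as many. The highest other gave 205, so chance was not excluded. Splits with far more calls than the real one point to a structure of the samples, which was not identified.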

How the results depend on the processing

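Setting values below 1 to 1 on every array was chosen after seeing the data and moved no count, list count or response size by over 1.5 times. Quantile normalization, listed as an alternative, became the main setting, and a floor at the 10th percentile was not run, as that percentile was -155 and has no logarithm. The cause was not tested for any change below except where stated.

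With scaled values 9 Gy over both sets gave 0 probe sets, and 1 week minus 1 day 1 probe set and 7 lists. Vitamin A gave 8 lists in the early and 1 in the 35-day set. With values as deposited 18 Gy minus 9 Gy gave 2 probe sets and 1 week minus 1 day 6 (8 lists). Vitamin A gave 1 (8 lists) in the early set, 1 in the 35-day set and 5 lists over both sets, and age gave 452. Crabp2 with vitamin A in the early set turned to -0.074 and the interaction of Aldh1a1 at 1 day to 0.13. With the floor at the 40th percentile (372) both 18 Gy contrasts gave 0, 1 week minus 1 day 7 lists, vitamin A in the early set 2, 9 Gy over both sets 2 and age 401. Cdkn1a then turned to -0.43 at 18 Gy, -0.65 for 18 Gy minus 9 Gy, -0.012 over both sets and 0.37 for the interaction at 1 week. Without a filter 9 Gy at 1 week gave 0, 18 Gy 69, 18 Gy minus 9 Gy 75, and 1 week minus 1 day 19. Vitamin A gave 15 in the early and 2 in the 35-day set (1 list), and 9 Gy over both sets 0. The interaction gave 732 (1 list) at 1 day and 308 at 1 week, and age 525, with more probe sets near the floor by construction. With a stricter filter vitamin A in the early set gave 2 and the interaction at 1 day 144. Without an intensity trend 9 Gy at 1 day gave 8, age 418, the interaction at 1 day 1 list and vitamin A in the 35-day set 0 lists. 9 Gy at 1 week, both 18 Gy contrasts, 1 week minus 1 day and 9 Gy over both sets gave 0. With a robust prior the interaction at 1 day gave 4. With a mean per group, which leaves 1 residual degree of freedom, 9 Gy at 1 day and 1 week, both 18 Gy contrasts and 1 week minus 1 day gave 0. The fed minus unfed response size at 1 day was -1.02, and Cdkn1a was at -1.11 for 18 Gy minus 9 Gy. Over both sets the alternative was a fit in which vitamin A and 9 Gy each had 1 effect common to both sets. It gave 3 probe sets for 9 Gy, with Cdkn1a at -0.15. With the mean over probe sets 1 week minus 1 day gave 6 lists. With an estimated correlation the 11 comparisons with lists called gave 0 lists each.

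Leaving out each array in turn moved the count from 0 to 428 for 9 Gy at 1 day (lists 5 to 8), 0 to 10 at 1 week (1 to 4), 0 to 134 at 18 Gy (0 to 4), 0 to 49 for 18 Gy minus 9 Gy (4 to 8) and 0 to 252 for 1 week minus 1 day (3 to 6). It ranged from 0 to 507 for vitamin A in the early set (3 to 8), 0 to 2 in the 35-day set (0 to 2) and 0 over both sets (2 to 5). It was 0 to 1 for 9 Gy over both sets (4 to 8). For age it was 853 to 1030 (5), over the 7 arrays that were not unfed controls. No control could be left out of that fit, so the range does not test how far age rests on single control pools. Response sizes ranged from -0.14 to -0.08 at 1 day and -0.14 to -0.06 at 1 week. No pool that enters the response at 1 day was left out for it. Of those that enter it at 1 week, only the controls at 35 days were. Cdkn1a ranged from -0.81 to 4.04 for 9 Gy at 1 day, -1.93 to 3.04 for 18 Gy, -1.12 to 3.85 for 18 Gy minus 9 Gy and -1.20 to 0.82 over both sets. Ccng1 ranged from -1.65 to 0.48 for 18 Gy, -1.37 to 0.75 for 18 Gy minus 9 Gy and -0.83 to 0.068 over both sets. Gadd45a ranged from -0.83 to 0.33 for 9 Gy at 1 day, -0.55 to 0.61 for 18 Gy and -0.79 to 0.36 for 1 week minus 1 day. Mdm2 at 1 week ranged from -0.79 to 0.26, Crabp2 with vitamin A in the early set from -0.013 to 0.27, the ribosomal list for 9 Gy at 1 day from -0.018 to 0.20, and the epidermal list at 18 Gy from -0.036 to 1.00. An array left out of a group of 1 pool leaves a contrast resting on fewer pairs, and in the fits within a set any early array but the 18 Gy one leaves the spread to the 35-day set. Of the values of named genes outside leave-one-out, 1334 kept direction and side of the threshold, 19 newly passed it, 169 no longer passed and 8 turned direction; for lists 419 were kept and 88 no longer passed. With single arrays left out, 1047 were kept, 44 newly passed, 304 no longer passed and 22 turned direction; for lists 359 were kept, 59 no longer passed and 3 turned direction.

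Leaving out single arrays ended further list calls, given in the report. Beside that and the estimated correlation, calls were lost under at least 1 other setting for the lymphocyte, mast cell and ribosomal lists at 1 day after 9 Gy and MHC class II genes at 18 Gy. They were also lost for cell cycle, protease and red blood cell genes for 18 Gy minus 9 Gy, macrophage genes at 1 week, over both sets and with vitamin A in the early set, both lists for vitamin A in the 35-day set, and the lists of the interaction other than the epidermal one.

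Signal over background limited the dim genes, with 1.39% to 2.82% of tested probe sets at the floor per array, the most in the 28-day control.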
